A study of Homo sapiens with 4 samples.

How the data were processed

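Expression of polyA RNA was measured in H23 cells, 2 control samples carrying GFP and 2 samples overexpressing SOX7, on Illumina HumanHT-12 v4 BeadChips after RNA isolation with RNeasy columns and biotin labelling, per the labels. The deposited values are log2 intensities of 48107 probes per array. The sorted values of the 4 arrays differed by at most 0.000683, so the values had been quantile normalized between the arrays by the authors. The software and any background correction are not given in the sources used here. No detection p-values and no background levels were used, so a signal near the array median was not separated from background, and the number of arrays limits the precision. All 4 columns were used, and none was put outside the groups.

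Probes were assigned to genes with the platform's annotation: 30113 carried 1 gene, 8 several and 17986 none. The gene identifiers of 30074 probes were found in the RefSeq annotation of assembly GRCh38.p14, and 0 symbols had to be updated. Genes without a name in this annotation are unnamed here and enter only as counts. For each of the 20046 named genes the probe with the highest mean was kept, 6691 genes having several probes. Genes whose mean lay below the median of all probe means (6.25 on the log2 scale) were left out, which left 12804.

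SOX7 and control arrays were compared with limma 3.58.1 (statmod 1.5.0, R 4.3.3), by a linear model per gene with moderated variances (residual degrees of freedom 2, moderated 11.7), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. Log2 fold changes are SOX7 minus control throughout, and values given in brackets after a gene are log2 fold changes unless named otherwise. For 1 gene the variance within the groups was 0. A set of 39 gene lists, each with at least 3 tested members, was compared with the other genes by camera with a preset correlation of 0.01, adjusted over the 39 lists, and counted also after adjustment over the list alone. The same lists were tested by camera with the correlation estimated from the residuals and by fry, which asks whether a list's genes move, on balance, one way and does not compare them with other genes. Of the 39 lists, 5 passed camera, 0 passed with an estimated correlation (lowest adjusted p = 0.584) and 4 passed fry; camera gave an unadjusted p under 0.05 for 10.

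The text names SOX7, SOX17, SOX18 and BCL2L11, then the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose arrays do not overlap. From each list it names up to 4 members with the smallest p where the list passed camera and up to 2 otherwise. The rule gave 104 genes. A further 43 genes that complete counts of 5 or fewer, and H4C3, H2AJ and MACROH2A2, were named after their values were seen. Other probes above the filter existed 47 times for genes the rule named that were past the threshold; 27 of them passed in the same direction, and 7 had the opposite sign without passing, with their values given beside the gene. For the 43 genes there were 15 such probes, of which 7 passed in the same direction and 1 had the opposite sign.

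The method was tested on simulated data with the sample numbers and spread of these arrays: 12804 genes of which 200 changed, in 20 runs. It recovered 92.9% of genes changed 1.5-fold and 100% of those changed 2-fold or 4-fold, with 5.22% false calls. No smaller change was simulated, although 77.2% of the genes past the threshold in these arrays changed by less than 1.5-fold. The variances were drawn from the distribution that limma fitted, so the share of false calls holds only under the model's own assumptions. A list of 20 genes raised by 0.3 was found in 20 of 20 runs with the preset correlation and in 0 of 20 with the estimated one. With the preset correlation, 0 of 780 unchanged lists were called. The simulated genes varied independently of each other, so this count cannot show how often unchanged lists of correlated genes are called. With an estimated correlation, a list of that size and shift thus could not be found at this number of arrays.

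Alternatives were no intensity filter, a filter at the 75th percentile, an offset of 16 on the linear values, the mean of a gene's probes, every probe on its own, a variance prior with a trend and robust estimation, the replicate number as a block, other thresholds, quantile normalization or median centring of the arrays, the 2 other set tests and leaving out each array in turn. Leaving out an array leaves 1 array in its group, which is then assumed to vary like the other group. Its brightest probes and filter are taken from the arrays left, and an alternative added later keeps the probes chosen from all 4. Another alternative added later removes the median change of the 101 genes around each gene along its chromosome. H1299 and PC14 samples named in the study's design were not analysed here.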

Results

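H23 cells, an established human line from a non-small cell lung cancer, were profiled after overexpression of SOX7, a transcription factor of the SOXF subfamily, or of green fluorescent protein (GFP) as the control. PolyA RNA from cells grown to near confluence was biotin-labelled and hybridised to Illumina HumanHT-12 v4 BeadChips, which read each transcript with short probes on beads. The 4 arrays fell into 2 control and 2 SOX7 samples. Each array held 48107 probe values on the log2 scale, with the same median of 6.26 and 75th percentile of 7.15 on every array. The 2 control arrays correlated at r = 0.995 across all probes, as did the 2 SOX7 arrays, and arrays of different groups at 0.990. Over the 12804 genes tested, the differences between arrays had an SD of 0.146 within the control pair and 0.150 within the SOX7 pair, against 0.296 to 0.308 between groups. The number of arrays limits the precision. The labels do not say whether the 2 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. H1299 and PC14 cells, which the study's design also names, were not analysed here.

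The comparison asks which transcripts differ between the samples labelled as overexpressing SOX7 and the control samples. EMP1, which encodes an epithelial membrane protein, rose 13.2-fold, from 6.31 ± 0.0046 to 10.04 ± 0.063 (log2 mean ± SD, n = 2; log2 fold change 3.72, SE 0.087; limma adjusted p = 3.64e-10). CCNA1, which encodes cyclin A1, rose 12.5-fold, and MMP10, a secreted matrix metalloproteinase, rose 11.03-fold. TM4SF18 rose 8.47-fold, the gap junction gene GJA1 (connexin 43) 6.55-fold, and RND3 6.43-fold. The next largest increases were in ALDH1A1, a retinaldehyde dehydrogenase (5.66-fold), CD34, a surface sialomucin of haematopoietic progenitors and endothelium (4.997-fold), HAS3, a hyaluronan synthase (4.91-fold), ZNF365 (4.39-fold), RTN1 (4.25-fold) and STEAP1 (3.88-fold). Standard errors of the log2 fold changes of these 12 genes ran from 0.087 to 0.11, and their adjusted p-values were at most 5.66e-08. Of these genes, 6 had a second probe above the intensity filter, which differed by 2.91 for TM4SF18, 2.66 for ALDH1A1, 1.67 for STEAP1, 1.18 for CD34 and 0.62 for HAS3 on the log2 scale. The second RTN1 probe differed by 0.031 and did not pass (limma adjusted p = 0.910 over all probes that carry 1 gene), against 2.09 for the first.

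Among the genes that fell, EVA1A, an endosomal and lysosomal membrane protein linked to autophagy, dropped 9.88-fold, from 10.24 ± 0.13 to 6.94 ± 0.097 (log2 mean ± SD, n = 2; log2 fold change −3.30, SE 0.098; adjusted p = 1.42e-09), with all 3 of its probes lower. DNER, a transmembrane protein with EGF-like repeats that binds Notch, fell 8.16-fold. AFAP1L2 fell 3.88-fold, CXXC5 3.74-fold and DKK3, a secreted protein of the Dickkopf family, 3.69-fold. The proteases PRSS23 and HTRA1 fell 3.33-fold and 2.70-fold. The crosslinking enzyme TGM2 fell 3.31-fold, the collagen gene COL5A1 3.18-fold, the protein kinase C substrate MARCKS 3.06-fold, the histone gene H2BC5 2.86-fold and the glutamate receptor subunit GRIN3B 2.80-fold. The 2 SOX7 arrays differed most for GRIN3B (7.95 ± 0.48), whose adjusted p of 7.24e-05 was the highest of these 12. No measure of detection was used, so a fold that starts or ends near the array median is not bounded by a background level. Among the genes above, this holds most closely for EMP1, CCNA1, ALDH1A1, CD34 and RTN1 in control cells and for DNER and COL5A1 in SOX7 cells. HTRA1 (6.76) and EVA1A (6.94) in SOX7 cells and MMP10 (6.90) in control cells lay next above. Genes named further below are also affected, among them HEY1 (6.14) and TNFAIP3 (6.63) in control cells. The same applies to TGFA (6.18), NOTCH3 (6.50) and IL6 (6.50) in SOX7 cells.

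The study's title concerns SOX7, MAPK/ERK signalling and apoptosis through BIM, the product of BCL2L11. The SOX7 probe read 6.31 ± 0.19 in the control arrays and 6.65 ± 0.18 in the arrays labelled SOX7 (log2 mean ± SD, n = 2), a difference of 0.34 (95% confidence interval 0.092 to 0.59) that did not pass the threshold (limma adjusted p = 0.0583). The single arrays read 6.18 and 6.45 in the control group and 6.53 and 6.78 in the SOX7 group. A second, dimmer SOX7 probe differed by 0.0039 on the log2 scale. Where these probes lie relative to the introduced transcript is unknown here, so they check neither the labels nor the level of SOX7 overexpression. The adjusted p of the SOX7 difference was 0.0487 with trend and robust prior, 0.00876 without control replicate 2, 0.0404 without SOX7 replicate 1, 0.299 without control replicate 1 and 0.322 without SOX7 replicate 2. The other members of the subfamily did not pass either, with differences of 0.026 for SOX17 (adjusted p = 0.907) and −0.13 for SOX18 (adjusted p = 0.406). SOX18 was the only 1 of the 3 far above the array median, at 10.004 ± 0.05 in the control arrays. As a list, 0 of 3 tested members rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.921). BCL2L11 read 6.23 ± 0.14 in the control and 6.50 ± 0.094 in the SOX7 arrays, a difference of 0.27 (95% confidence interval 0.057 to 0.49) that did not pass (adjusted p = 0.0769) and passed without control replicate 1 (adjusted p = 0.0342). Its other 2 probes differed by 0.065 and −0.059, and all 3 lay close to the median of the array.

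**Figure D1:**
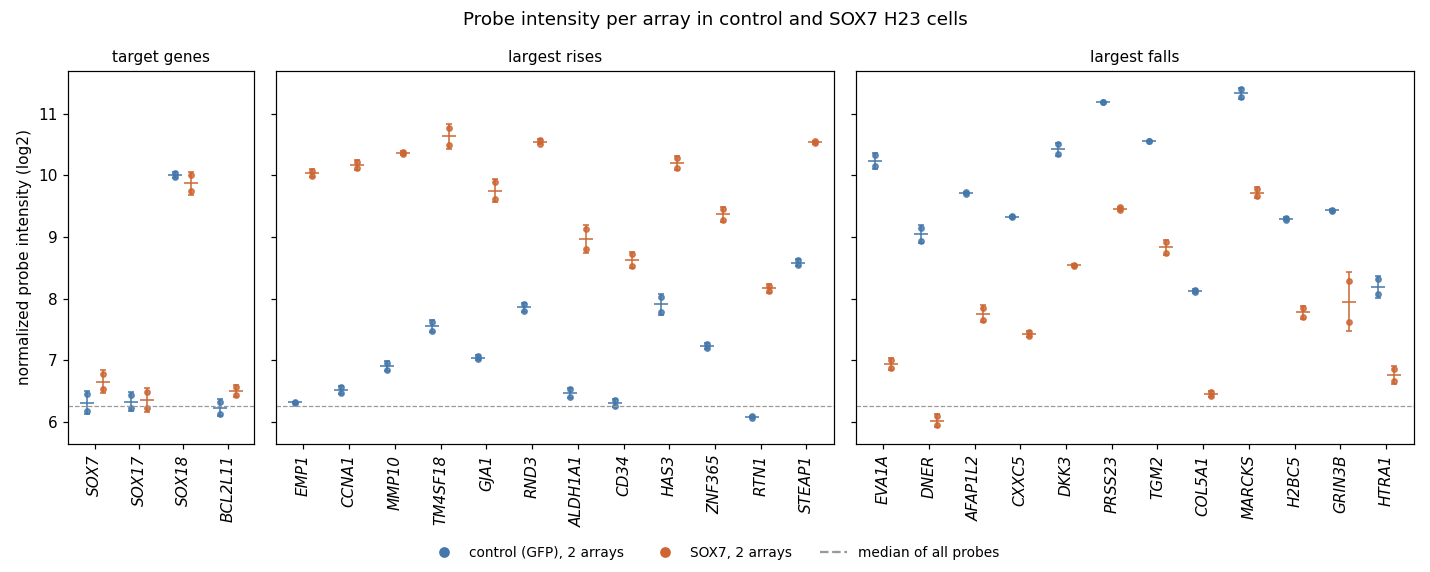
Normalized log2 probe intensity (vertical axis) of SOX7, SOX17, SOX18 and BCL2L11, of the 12 genes with the largest rises and of the 12 with the largest falls (horizontal axis), in control and SOX7 H23 cells. Points are single arrays (2 per group), dashes with bars are the mean ± SD and the dashed line is the array median of 6.26; EMP1 lies at 6.31 in control and 10.04 in SOX7 cells, while SOX7 itself lies at 6.31 and 6.65.

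Across the 12804 genes tested, 2408 (18.8%) passed a Benjamini-Hochberg adjusted p of 0.05, 1150 higher and 1258 lower in SOX7 cells. At least a 2-fold change was seen in 122 of them, 73 higher and 49 lower, and at least a 4-fold change in 11 higher and 2 lower. The median change among the 2408 was 1.33-fold, and 1859 (77.2%) changed by less than 1.5-fold. In all 2408 the arrays of the groups did not overlap, as was the case for 58.5% of all genes tested, where chance gives 33.3%. The count fell to 1567 without SOX7 replicate 1 (711 higher) and to 1529 without SOX7 replicate 2 (721 higher and 808 lower). Genes that neighbour each other on a chromosome shifted together, and with the median of 101 neighbouring genes removed (neighbour-centred) 2189 genes passed, 1971 of them among the 2408. The strongest such stretches, at most 1 per direction on a chromosome, numbered 10 beyond the range of shuffled genes and held 18 of the genes named here. These were PHLDA1, DUSP6, LUM, APAF1, TXNRD1, ALDH1A1, DNAJA1, UCHL1, CXCL8, CXCL1, GJA1, HEY2, CCN2, TNFAIP3 and the falling COL3A1 in stretches that were higher, and UBE2C, PMEPA1 and TNFRSF12A in stretches that were lower. Neighbour-centred, 15 of the 18 still passed, among them PHLDA1 (0.87), TXNRD1 (0.82), CXCL8 (1.13), CXCL1 (1.02) and TNFAIP3 (0.93), and APAF1, DNAJA1 and UBE2C did not.

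Genes of the transcriptional output of MAPK/ERK signalling were higher in SOX7 cells as a list. Of 23 tested members, 11 rose and 2 fell (12 and 2 adjusted over the list alone), with a median log2 fold change of 0.23 (camera adjusted p = 5.31e-05). The list no longer passed with the correlation between genes estimated from these arrays (adjusted p = 0.646 with an estimated correlation). After EMP1, the rises with the smallest p were in the cytokine gene CXCL8 (1.23), the feedback inhibitor SPRY1 (1.11) and PHLDA1 (1.01), each at least 2.01-fold. TGFA (−0.71), which encodes an EGF receptor ligand, and EPHA2 (−0.28), a receptor tyrosine kinase, fell. The call was lost when 1 array was left out for EPHA2 (adjusted p = 0.200 without SOX7 replicate 1, and lost without each of the 4 arrays). Of the phosphatases that act on MAP kinases, 1 of 7 tested members rose and 1 fell (1 and 1 adjusted over the list alone), DUSP6 by 0.68 and DUSP1 by −0.45 (camera adjusted p = 0.941). The call of DUSP1 ended without SOX7 replicate 1 (adjusted p = 0.0841), and the list's median of −0.015 and mean of 0.053 had opposite signs. Of the RAS-RAF-MEK-ERK cascade itself, 0 of 16 tested members rose and 3 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.954). The members that fell were MAPK3, which encodes ERK1 (−0.58), the receptor ERBB2 (−0.45, with a second probe at 0.0033) and the adaptor SHC1 (−0.30). The call was lost on leaving out 1 array for SHC1 (adjusted p = 0.172 without SOX7 replicate 1, and lost without each of the 4 arrays). The cascade list had a median of 0.027 and a mean of −0.030. Among immediate early genes, 5 of 20 tested members rose and 2 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.171). EGR1 (0.85), NR4A2 (0.60), FOS (0.41), FOSB (0.38) and ATF3 (0.35) rose, and ZFP36L1 (−0.71) and JUND (−0.34) fell. Leaving out 1 array ended the calls of FOS (adjusted p = 0.0684 without SOX7 replicate 1), FOSB (adjusted p = 0.0920 without SOX7 replicate 2, and lost without control replicate 1), ATF3 (adjusted p = 0.165 without control replicate 1, and lost without SOX7 replicate 1 or SOX7 replicate 2) and JUND (adjusted p = 0.217 without control replicate 2, and lost without SOX7 replicate 1 or SOX7 replicate 2).

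Apoptosis genes moved in both directions, and none of their lists passed. Of the pro-apoptotic BCL2 family, 1 of 11 tested members rose and 1 fell (1 and 1 adjusted over the list alone), namely PMAIP1, which encodes NOXA (0.90, SE 0.092, adjusted p = 4.34e-05), and BNIP3L (−0.53, adjusted p = 0.00115). The list's camera adjusted p was 0.652. Of the anti-apoptotic members, 0 of 5 tested members rose and 0 fell (0 and 0 adjusted over the list alone), with differences of 0.25 for MCL1 (adjusted p = 0.0748; second probe 0.63) and 0.16 for BCL2A1 (adjusted p = 0.232) and a camera adjusted p of 0.881. MCL1 passed for the mean of its probes, at 0.44 (adjusted p = 0.00309, in a range of 0.00309 to 0.285 over its alternatives), at the 75th percentile filter (0.0325) and with trend and robust prior (0.0256). Its second probe passed on its own (limma adjusted p = 0.00146 over all probes that carry 1 gene). Of the caspases, inhibitor of apoptosis proteins and apoptosome genes, 3 of 15 tested members rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.922). CYCS, the gene of cytochrome c (−0.49), and the mitochondrial protease HTRA2 (−0.44) fell, while APAF1 (0.51), BIRC2 (0.44) and CASP9 (0.30) rose. Calls lost when 1 array was left out were those of APAF1 (adjusted p = 0.0870 without SOX7 replicate 2) and CASP9 (adjusted p = 0.223 without control replicate 1, and lost without SOX7 replicate 1 or SOX7 replicate 2). Neither passed for the mean of its probes, at 0.26 for APAF1 and 0.18 for CASP9, and APAF1 did not pass neighbour-centred (0.34). Of the death receptors and their ligands, 2 of 9 tested members rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.954; median −0.088, mean 0.010). TNFRSF10A, a TRAIL receptor (0.58), and TNFRSF21 (0.42) rose. TNFRSF12A (−0.38) and TRADD (−0.35), an adaptor that the list also holds, fell. In fits without 1 array, the call was lost for TNFRSF12A (adjusted p = 0.0801 without SOX7 replicate 1, and lost without control replicate 2) and TRADD (adjusted p = 0.127 without SOX7 replicate 2, and lost without control replicate 1).

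Inflammatory, amino acid stress and antioxidant genes were higher as lists. Of the NF-kB and cytokine genes, 10 of 20 tested members rose and 1 fell (11 and 2 adjusted over the list alone; camera adjusted p = 1.98e-04). This list did not pass with the other set tests (adjusted p = 0.762 with an estimated correlation; fry adjusted p = 0.0708). The chemokines CXCL8 (1.23), CCL20 (1.196) and CXCL1 (1.11) and TNFAIP3, which encodes the NF-kB inhibitor A20 (1.05), each rose over 2-fold, and IL6 fell (−0.60). Of the ATF4/CHOP stress genes, 11 of 22 tested members rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 6.43e-05), again with no call by the other tests (adjusted p = 0.762 with an estimated correlation; fry adjusted p = 0.0652). The amino acid transporter subunits SLC7A5 (1.15) and SLC3A2 (0.80), the pseudokinase TRIB3 (0.90) and DDIT3, the gene of CHOP (0.70), rose, and DDIT4 fell (−0.33). The call ended on leaving out 1 array for DDIT4 (−0.22, adjusted p = 0.242 without SOX7 replicate 2, and lost without control replicate 1). Of the NRF2 targets, 8 of 16 tested members rose and 1 fell (11 and 2 adjusted over the list alone; camera adjusted p = 4.43e-04; adjusted p = 0.646 with an estimated correlation). TXNRD1 (0.94), HMOX1 (0.75) and GCLM (0.73), genes of thioredoxin, haem and glutathione metabolism, rose, and the transporter ABCC3 fell 2.37-fold (−1.25). The MAPK/ERK and NF-kB lists share CXCL8 and LIF, and the ATF4/CHOP and NRF2 lists share SLC7A11.

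Other stress and metabolic lists did not pass. Of the heat shock genes, 4 of 14 tested members rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.145). HMOX1, HSPH1 (0.43), HSPA6 (0.36) and DNAJA1 (0.34) rose and HSPA1A (−0.30) fell. Calls lost without 1 array were those of HSPH1 (adjusted p = 0.0597 without SOX7 replicate 2), DNAJA1 (adjusted p = 0.129 without SOX7 replicate 2, and lost without control replicate 1 or control replicate 2) and HSPA1A (adjusted p = 0.190 without control replicate 1, and lost without SOX7 replicate 1 or SOX7 replicate 2). HSPA6 lost its call without control replicate 2 (adjusted p = 0.0543) and, with its probe kept, without SOX7 replicate 2 (0.28, adjusted p = 0.133). Of the ER chaperone and unfolded protein genes, 0 of 17 tested members rose and 1 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.881). EDEM1 was the member that fell (−0.30), with a call lost without each of the 4 arrays (adjusted p = 0.138 without SOX7 replicate 2), while PDIA4 differed by −0.26 (adjusted p = 0.0679). PDIA4 passed at the 75th percentile filter (0.0283) and for the mean of probes (0.0484), in a range of 0.0283 to 0.298 over its alternatives. Of the hypoxia and glycolysis genes, 3 of 23 tested members rose and 7 fell (3 and 8 adjusted over the list alone; camera adjusted p = 0.652). NDRG1 (−0.61) and the glycolytic enzyme gene ALDOA (−0.58) fell furthest, and HK2 (0.62), PFKFB3 (0.37) and SLC2A3 (0.32) rose. Leaving out 1 array ended the calls of PFKFB3 (adjusted p = 0.0858 without SOX7 replicate 2) and SLC2A3 (0.20, adjusted p = 0.251 without SOX7 replicate 1, and lost without control replicate 1 or control replicate 2). Of the cholesterol synthesis genes, 2 of 17 tested members rose and 0 fell (0 and 0 adjusted over the list alone), namely HMGCS1 (0.31) and DHCR7 (0.31; camera adjusted p = 0.652). Neither call held in every fit without 1 array: HMGCS1 (adjusted p = 0.208 without control replicate 1, and lost without SOX7 replicate 1 or SOX7 replicate 2) and DHCR7 (adjusted p = 0.213 without SOX7 replicate 1, and lost without control replicate 1). Of the interferon response genes, 7 of 24 tested members rose and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.146). HERC5 (0.67) and the peptide transporter gene TAP1 (0.69) rose, and IRF9 fell (−0.38), a call that ended without SOX7 replicate 2 (adjusted p = 0.0505).

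PolyA transcripts of replication-dependent histone genes fell together. The arrays read polyA RNA, so transcripts of these genes without a polyA tail were not measured. Of 14 tested members, 13 fell and 0 rose, over all genes and also adjusted over the list alone, with a median log2 fold change of −0.78 (camera adjusted p = 1.21e-12). The list was past the threshold by fry (adjusted p = 0.0171) and not when the correlation was estimated (adjusted p = 0.584 with an estimated correlation). The largest falls were 2.86-fold for H2BC5, 2.33-fold for H2BC21, 2.19-fold for H2AC6 and 2.11-fold for the linker histone gene H1-2, and H4C3 was the member that did not pass (0.092). Genes of DNA replication and S phase showed no such shift: 0 of 28 tested members rose and 2 fell (0 and 0 adjusted over the list alone), with a median of 0.024 (camera adjusted p = 0.952). PCNA (−0.35) and E2F1 (−0.44) were those that fell. Calls that fits without 1 array did not keep were those of PCNA (adjusted p = 0.157 without SOX7 replicate 2, and lost without control replicate 1) and E2F1 (−0.23, adjusted p = 0.230 without SOX7 replicate 1, and lost without control replicate 1). Of the G2/M and mitosis genes, 4 of 30 tested members rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.171). The mitotic genes KIF2C (0.41), PLK1 (0.39), CENPE (0.35) and BUB1 (0.35) rose and UBE2C (−0.33) fell. None of these 5 calls held in every fit without 1 array: KIF2C (adjusted p = 0.0508 without control replicate 1), PLK1 (adjusted p = 0.0941 without SOX7 replicate 2), CENPE (adjusted p = 0.0700 without SOX7 replicate 2, and lost without control replicate 1), BUB1 (adjusted p = 0.0731 without SOX7 replicate 1, and lost without control replicate 1 or SOX7 replicate 2) and UBE2C (−0.21, adjusted p = 0.260 without control replicate 2, and lost without SOX7 replicate 1 or SOX7 replicate 2). Of the CDK inhibitors, 1 of 7 tested members rose and 0 fell (2 and 0 adjusted over the list alone), CDKN1B by 0.29 (camera adjusted p = 0.354), but its second probe differed by −0.20 and the call was lost without each of the 4 arrays (adjusted p = 0.256 without SOX7 replicate 2). CDKN2A differed by 0.26 (adjusted p = 0.0615) and passed at the 75th percentile filter (0.0251), with the offset (0.0434) and with trend and robust prior (0.0244), in a range of 0.0244 to 0.927 over its alternatives.

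**Figure D2:**
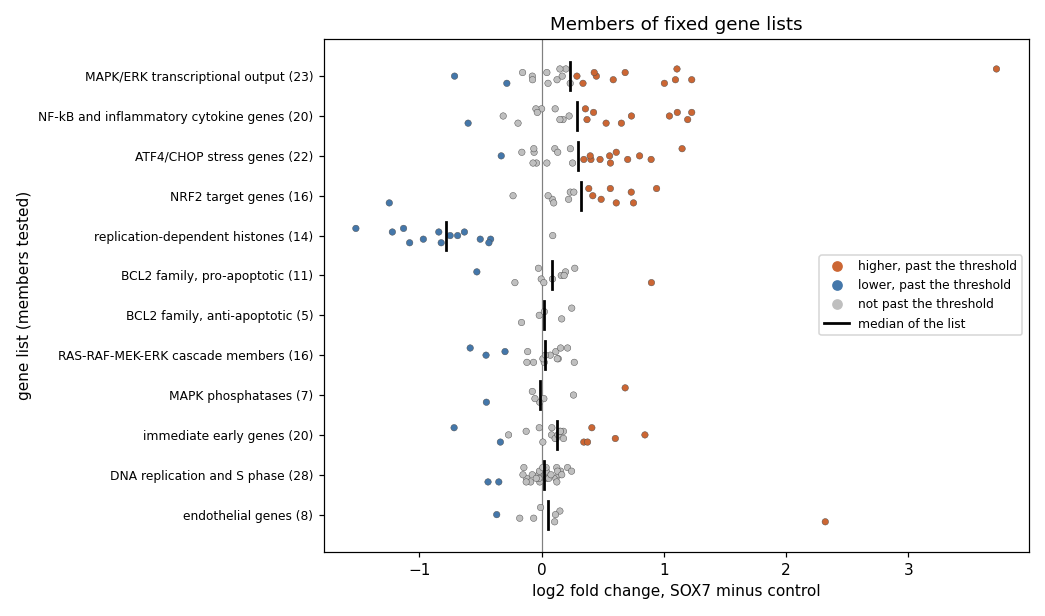
Log2 fold change, SOX7 minus control (horizontal axis), of the tested members of 12 of the 39 gene lists (vertical axis, with the number of members tested). Points are genes, coloured where they passed a limma adjusted p of 0.05, and black bars are list medians. In polyA RNA, the replication-dependent histones centre on −0.78 while the DNA replication and S phase genes centre on 0.024.

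Lists of other signalling pathways held large changes in single genes without passing as lists. Of the Notch pathway genes, 3 of 13 tested members rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.171). The ligand gene JAG1 (0.98) and the target genes HEY1 (1.003) and HEY2 (0.88) rose, while the receptor gene NOTCH3 fell 2.23-fold. A second HEY1 probe differed by −0.036. Of the Wnt/beta-catenin targets, 2 of 13 tested members rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.146). The Wnt inhibitor gene DKK1 rose 2.22-fold, AXIN2 rose (0.41) and the hyaluronan receptor gene CD44 fell (−0.56). Leaving out 1 array ended the call of AXIN2 (0.26, adjusted p = 0.145 without control replicate 1, and lost without SOX7 replicate 1 or SOX7 replicate 2). Of the p53 targets, 2 of 19 tested members rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.922). PMAIP1 (0.90) and AEN (0.45) rose, and TP53I3 (−0.56), TP53INP1 (−0.39) and DDB2 (−0.29) fell. A second TP53I3 probe differed by 0.046. In fits without 1 array, the call was lost for AEN (adjusted p = 0.0611 without SOX7 replicate 1), TP53INP1 (−0.22, adjusted p = 0.229 without SOX7 replicate 2) and DDB2 (adjusted p = 0.234 without control replicate 1, and lost without SOX7 replicate 1 or SOX7 replicate 2). Of the FOXO targets, 1 of 15 tested members rose and 2 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.954; median 0.060, mean −0.034). CDKN1B rose as given above, and PIK3IP1 (−0.67) and IRS2 (−0.38) fell. The call was lost on leaving out 1 array for IRS2 (adjusted p = 0.0957 without SOX7 replicate 2, and lost without control replicate 1). Of the TGF-beta targets, 3 of 15 tested members rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.954; median 0.040, mean −0.0074). BHLHE40 (−0.61) and PMEPA1 (−0.48, with a further probe at 0.010) fell, and LTBP2 (0.42), CCN2 (0.37) and ID3 (0.28) rose. Of the YAP/TAZ targets, 1 of 16 tested members rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.881). CCN2 rose, and PTPN14 (−0.49, with a second probe at 0.21) and CRIM1 (−0.34) fell. In these last lists, leaving out 1 array ended the calls of CCN2 (adjusted p = 0.0943 without SOX7 replicate 1, and lost without control replicate 1), ID3 (adjusted p = 0.161 without SOX7 replicate 2, and lost without each of the 4 arrays) and CRIM1 (−0.22, adjusted p = 0.215 without SOX7 replicate 1, and lost without control replicate 1 or control replicate 2).

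Matrix and lineage genes also moved in both directions. Of the extracellular matrix and protease genes, 3 of 19 tested members rose and 6 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.869; median 0.023, with a camera direction of down). MMP10 rose as given above, with MMP1 (1.04) and COL4A1 (0.53), while COL5A1 (−1.67) and COL3A1 (−1.18) fell. Of the mesenchymal genes of the epithelial-mesenchymal transition, 1 of 14 tested members rose and 3 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.881). CDH2, which encodes N-cadherin, rose 2.30-fold, and COL5A1, S100A4 (−1.22) and TNC (−0.39) fell. Of the epithelial genes, 3 of 10 tested members rose and 0 fell (3 and 0 adjusted over the list alone), namely KRT18 (0.45), CLDN3 (0.42) and ELF3 (0.39; camera adjusted p = 0.199). This list passed at the 75th percentile filter (adjusted p = 0.0247, in a range of 0.0247 to 0.762 over its alternatives). Of the endothelial genes, 1 of 8 tested members rose and 1 fell (1 and 1 adjusted over the list alone), with CD34 higher and ENG lower (−0.37; camera adjusted p = 0.869). Another 18 members lay below the intensity filter. Of the lung epithelial genes, 0 of 7 tested members rose and 1 fell (0 and 1 adjusted over the list alone), with ABCA3 lower (−0.31) and FOXA1 at 0.18 (adjusted p = 0.190; list camera adjusted p = 0.954). Leaving out 1 array ended the calls of TNC (−0.26, adjusted p = 0.152 without control replicate 1, and lost without SOX7 replicate 2), ENG (adjusted p = 0.0554 without SOX7 replicate 2) and ABCA3 (adjusted p = 0.226 without SOX7 replicate 2, and lost without control replicate 1). Without SOX7 replicate 1 the brightest TNC probe changed (−0.76), and with its probe kept the call was lost there (−0.41, adjusted p = 0.0615). None of the 4 marker lists of other cell types passed. Of the fibroblast markers, 2 of 6 tested members rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.954), with LUM (0.52) and MFAP5 (0.54) higher and COL3A1 lower. Of the haematopoietic markers, 1 of 7 tested members rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.881), with CD14 (0.64) higher and CD68 (−1.04) lower. Of the neuroendocrine markers, 2 of 8 tested members rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.150), namely SCG2, a granin (2.69-fold), and UCHL1 (2.02-fold). This list passed by fry (adjusted p = 0.0469) and at the 75th percentile filter (0.0128, in a range of 0.0128 to 0.762 over its alternatives). Of the squamous and basal markers, 0 of 3 tested members rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.652), with SERPINB5 at 0.18 (adjusted p = 0.203) and DSC3 at 0.17 (adjusted p = 0.243; second probe −0.23). The MFAP5 call ended without SOX7 replicate 2 (adjusted p = 0.0613).

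Genes of general cell function showed no shift as lists. Of the cytosolic ribosomal protein genes, 1 of 34 tested members rose and 2 fell (0 and 2 adjusted over the list alone; camera adjusted p = 0.774). RPL13 (−0.50, with a second probe at 0.16) and RPL22 (−0.41) fell and RPL4 rose (0.29). Of the oxidative phosphorylation genes, 0 of 30 tested members rose and 3 fell (0 and 1 adjusted over the list alone), namely SDHA (−0.40), NDUFB5 (−0.29) and COX6C (−0.27; camera adjusted p = 0.881; median 0.0031, mean −0.023). Of 12 common reference genes, POLR2A rose (0.52) and SDHA and PPIA (−0.33) fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.954). Calls that fits without 1 array did not keep were those of RPL4 (adjusted p = 0.185 without control replicate 1, and lost without SOX7 replicate 1 or SOX7 replicate 2), SDHA (adjusted p = 0.0659 without SOX7 replicate 2, and lost without control replicate 1), NDUFB5 (adjusted p = 0.140 without control replicate 2, and lost without each of the 4 arrays), COX6C (adjusted p = 0.150 without SOX7 replicate 1, and lost without each of the 4 arrays) and PPIA (adjusted p = 0.0796 without SOX7 replicate 1, and lost without control replicate 2 or SOX7 replicate 2).

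Some of the calls above rested on the probe or the setting. For the mean of a gene's probes, calls were also lost for CDKN1B (0.042), DHCR7 (0.16), ERBB2 (−0.13), HSPA6 (0.14), PMEPA1 (−0.24), PTPN14 (−0.14), RPL13 (−0.17), SHC1 (−0.23) and UBE2C (−0.21), and ATF3 lay at −0.0012. Further probes above the filter had the sign of the gene's call without passing for PMAIP1 (0.21), PHLDA1 (0.21), DUSP6 (0.19), GCLM (0.18), CCN2 (0.34), DHCR7 (0.017), ALDOA (−0.34), HTRA2 (−0.30), PCNA (−0.23), PMEPA1 (−0.36) and CD68 (−0.29 and −0.28). The same held for APAF1 (0.0033), CASP9 (0.068), CENPE (0.17), HK2 (0.33), SHC1 (−0.15), TRADD (−0.32) and UBE2C (−0.096), and a second HSPA6 probe had the opposite sign (−0.080). Neighbour-centred, calls were also lost for BUB1 (0.21), EDEM1 (−0.18), HMGCS1 (0.20), UBE2C (−0.20), TRADD (−0.27), DNAJA1 (0.27), ATF3 (0.26), CDKN1B (0.25), E2F1 (−0.38), DDIT4 (−0.28), DHCR7 (0.29), ABCA3 (−0.27), EPHA2 (−0.27), HSPA1A (−0.27) and NDUFB5 (−0.27). A fit without the intensity filter adjusts over more genes and estimates the moderated variances anew, and it leaves the differences as they are. Without the filter, calls were lost for PCNA, E2F1, CDKN1B, EDEM1, HMGCS1, DHCR7, ABCA3, NDUFB5, ATF3, CASP9, COX6C, CRIM1, DDB2, DDIT4, EPHA2, HSPA1A, ID3, JUND, RPL4, SHC1, SLC2A3, TP53INP1 and UBE2C.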

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

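The test of the probes without a gene name was chosen after the named genes had been seen. Probes with no gene or with several genes in the annotation take no part in the comparisons above, and 6954 of them lay at or above the intensity filter. Of these, 171 (2.46%) passed limma's adjusted p of 0.05 when SOX7 and control cells were compared, 86 higher and 85 lower in SOX7 cells. The adjustment was made over these 6954 probes alone. At least a 2-fold change was seen for 6 higher and 2 lower probes, with a largest rise of 3.84-fold and a largest fall of 2.17-fold. What these probes read is unnamed here, and no explanation was tested.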

How the results depend on the processing

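The alternatives were chosen before the data were examined, except the removal of the shift of the 101 neighbouring genes and the fits that keep the probes when an array is left out, which were chosen after seeing the data. Quantile normalization and median centring move nothing by construction, since the arrays share 1 distribution. The count of genes past the threshold was 2408 of 12804 and 1775 without a filter, 3343 at an adjusted p of 0.1 and 122 where a 2-fold change was also asked for. It was 2642 at the 75th percentile filter, 2655 with the offset, 2304 for the mean of probes, 2914 with trend and robust prior and 2189 neighbour-centred, of which 1948, 2377, 1987, 2335 and 1971 were among the 2408. Leaving out 1 array gave 1529 to 1984 genes, 711 to 985 higher and 808 to 999 lower; without control replicate 1 the count was 1879, without control replicate 2 1984, without SOX7 replicate 1 1567 and without SOX7 replicate 2 1529. The arrays form 3 splits into pairs, too few for a share under 0.05. The real split gave 2408 genes and the highest other 0 by limma (74 and 72 at an unadjusted p under 0.05), so only the real split itself reached that count. The other splits mix the groups, which puts the difference between SOX7 and control into the residual. They were therefore bound to call few genes. Of the 136 named genes past the threshold, 85 stayed past it under every alternative run for single genes and 47 lost it without 1 array; H2AJ and MACROH2A2 are not counted here, and MACROH2A2 lost it without control replicate 2 (adjusted p = 0.142) or SOX7 replicate 2 (0.219).

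SOX7 passed with trend and robust prior (0.34, adjusted p = 0.0487) and without control replicate 2 or SOX7 replicate 1; over all alternatives its difference ran from 0.17 to 0.48 and its adjusted p from 0.00876 to 0.322, and over the fits without 1 array its difference ran from 0.21 to 0.48. BCL2L11 ran from 0.13 to 0.37 over all alternatives (adjusted p 0.0342 to 0.413) and from 0.17 to 0.37 without 1 array. Replicate numbers do not pair the arrays (correlation −0.0173 over genes, 2 pairs); with the replicate block the count was 2834, SOX7 stood at 0.34 (adjusted p = 0.00906) and BCL2L11 at 0.27 (adjusted p = 0.0497). Neither gene has a value under the 75th percentile filter, which leaves both out, and BCL2L11 has none for the mean of probes. Without 1 array SOX17 ran from −0.11 to 0.16, DSC3 from −0.20 to 0.27 and HSPA6 from −0.039 to 0.44. These fits choose the brightest probe again, which changed it for DSC3 and HSPA6 without SOX7 replicate 2 and for TNC without SOX7 replicate 1; with the probe kept, DSC3 stood at 0.075, HSPA6 at 0.28 and TNC at −0.41. With all probes kept, 1486 to 1937 genes passed without 1 array. For the mean of probes DSC3 was −0.030 and ATF3 −0.0012, where dimmer probes enter the mean.

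The number of lists past the threshold was 5, with 0 for the estimated correlation, 4 by fry and 7 at the 75th percentile filter. The MAPK/ERK output list had an adjusted p of 0.646 with an estimated correlation, in a range of 2.04e-06 to 0.646 over its alternatives. The pro-apoptotic BCL2 list ran from 0.0820 to 0.926 and never passed. The lists that changed direction did so far from the threshold, and the cause was not tested. Their adjusted p without 1 array ran from 0.654 to 0.999 for SOXF factors, 0.734 to 0.981 for caspases, 0.945 to 0.978 for reference genes, 0.945 to 0.986 for death receptors, 0.879 to 0.992 for S phase, 0.925 to 0.978 for lung epithelial genes, 0.838 to 0.955 for the RAS cascade, 0.945 to 0.998 for TGF-beta and 0.489 to 0.955 for YAP/TAZ. Death receptors turned without a filter (0.995), at the 75th percentile (0.938), with the replicate block (0.986), by fry (0.904) and neighbour-centred (0.999). TGF-beta targets turned with the replicate block (0.986) and by fry (0.823), and matrix genes by fry (0.749). Haematopoietic markers turned without a filter (0.972), lung epithelial genes at the 75th percentile (0.524) and for the mean of probes (0.959), and S phase genes for the mean of probes (0.982). Of all values under alternatives, 1855 of single genes kept side and direction, 14 moved past the threshold, 165 back and 6 turned; for lists these were 545, 3, 7 and 26. Signal over background is unknown, which limits every value near the array median of 6.26.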

Other observations

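All tests in this part were chosen after the results they examine were seen. Of 50 histone genes tested, 25 fell and 0 rose in SOX7 cells (limma), and of the 36 outside the fixed list, which were not tested as a group, 12 fell. Of 10 genes of variant histones among these, 2 fell and 0 rose, with log2 fold changes from −0.79 to 0.24. Those that fell were H2AJ (−0.79) and MACROH2A2 (−0.36), the latter with no call without control replicate 2 (adjusted p = 0.142) or SOX7 replicate 2 (adjusted p = 0.219). Among 221 families of genes sharing a name stem, the stem H alone passed camera (adjusted p = 5.19e-07, and 0.956 with an estimated correlation). This stem holds the histone genes above without MACROH2A1 and MACROH2A2, and also other genes. It includes the members of the fixed list, so it is not a separate test of them. Of the 22 genes tested with the stem NUP, used for nucleoporins, 7 rose and 0 fell (camera adjusted p = 0.0541), and of the 161 TMEM genes, a mixed set of membrane proteins, 6 rose and 37 fell (camera adjusted p = 0.0619); neither family passed.

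Genes that neighbour each other on a chromosome in assembly GRCh38.p14 shifted together. In windows of 101 tested genes, the stretch from CCDC12 to SPCS1 had a median log2 fold change of −0.20, with 33 genes lower and 1 higher, and that from FAM83D to GNAS −0.14, with 29 lower and 8 higher. The stretch from RAB21 to CRY1 had a median of 0.19, with 37 higher and 4 lower, that from HOXD4 to FZD5 0.17, with 25 higher and 5 lower, and that from DNAJA1 to TLE1 0.13, with 31 higher and 4 lower. Window medians of shuffled genes ran from −0.10 to 0.12.

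The shift of neighbouring genes was larger than chance placement gives, with a spread of window medians 2.41 times that of shuffled genes. Random variation between the 2 arrays of a group is argued against by the same ratio within the groups, at most 1.11. Such pairs may be technical and cannot show variation between cultures or preparations that differs between the groups, so that source stays open. A trend over gene length is argued against by the ratio of 2.36 that was left once that trend was removed. Co-regulation of adjacent genes only is argued against by genes 50 to 100 places apart, whose fold changes correlated at a Spearman rho of 0.0435 against at most 0.0094 after shuffling (across genes, which are not independent replicates). A copy number difference between the control and SOX7 cells may underlie part of the shift and stays open, as no DNA measurement was analysed here. The ratio of 1.82 among genes not past the threshold cannot decide it, since those genes were chosen by their own change. Broad regulation after SOX7 overexpression also stays open and was not tested.

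The fall of the replication-dependent histones, read in polyA RNA only, had a median of −0.78. Fewer cells in S phase stays open. The S phase list had a median of 0.0241 with an SD of 0.156 over its members, so those genes did not fall as the histones did. How far they would move with the share of cells in S phase was not measured, so the list cannot decide it. A single transcript read by all histone probes stays open, although the SD of the members' fold changes was 4.42 times their median SE. That SE holds only the spread between arrays, and probes of the same gene can differ by more. Those of TGM2 read −1.73, −0.82 and −0.51, with an SE of at most 0.12, so the ratio cannot decide it. A general fall of short transcripts over all intensities is argued against by 10000 lists of other genes matched in length. Their medians centred on 0.0173 and were as low in 0 cases (lowest −0.26). These lists were not matched in intensity, so they cannot speak for bright short transcripts alone. A change in histone transcription or in the share of histone transcripts that carry a polyA tail could give the fall of the histone list, and neither was tested.

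The SOX7 probe lay near the array median in both groups. The highest SOX7 probe value in the SOX7 arrays was 6.78, below the 75th percentile of 7.15, as it would be if the probes lie outside the introduced transcript, and no probe or construct sequence was used to decide this. An exchange of the control and SOX7 labels cannot be told apart from the stated labels with the SOX7 probes, since the dimmer probe differed by 0.0039 and the brighter by 0.34 with an adjusted p of 0.0583 (0.00876 to 0.322 over its alternatives). The level of SOX7 overexpression is likewise not shown by these probes, and no biological explanation was tested for this pattern.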
